A study of Mus musculus and Homo sapiens with 3 samples.

How the data were processed

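Degradome libraries were made from poly(A)+ RNA of mouse cerebellum, mouse testis and H1 cells by global 5′ RACE, per the labels' protocols: an adapter was ligated to free 5′ ends, cDNA was primed with random hexamers and amplified in 25 PCR cycles. Each group had 1 library. The 2 mouse RNAs were bought as total RNA, per the labels, and how many animals they came from is not stated there. The processing named cutadapt, a tool that trims adapters, and the builds mm10 and hg19, per the submitters' processing notes, which give no roles or order here. The build mm10 was taken for the mouse libraries and hg19 for H1. The aligner, the handling of duplicate reads and of reads that match several places, and the way a position was called are not given in the sources used here.

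The files deposited by the authors hold intervals of 1 to 4 bases with a chromosome, start, end and strand, and their other columns are empty. Their unit is a listed interval, with no count, score or p-value attached. Single bases made up 63.0% of cerebellum entries, 64.9% of testis entries and 66.6% of H1 entries. The cerebellum library held 214332 entries, of which 70 overlapped another on the same strand, the testis library 137437 and the H1 library 129112. The depth in reads is unknown, and the precision given here is that of the number of positions.

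Each entry was reduced to its 5′ base, numbered from 1. Mouse positions were set against 49980 gene spans of a RefSeq table of GRCm38.p6, whose coordinates are those of mm10. A position was assigned to a gene when it lay inside the span of exactly 1 gene, on either strand, because the table gives spans without exons or strand. This left 185910 cerebellum and 108257 testis positions assigned to 1 gene. The plan made before the data were examined had been to count reads in exons on the sense strand. Read counts, exon classes and untranslated regions, base composition around the positions, and genes of H1 with its 2 preset lists were therefore not analysed here.

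Levels are positions relative to the total of the library. With 1 library per group, genes were listed by a rule of size set before the data were examined: at least 30 positions over both libraries and a 95% conditional exact (Clopper-Pearson) interval of the ratio wholly beyond 4-fold. A gene with 0 positions in a library was given the bound that 3 positions in that library allow. Log2 ratios had 5 positions per 1000000 added on both sides, which understates the ratio of low genes. For the comparison of cerebellum with testis, data were simulated as independent Poisson counts with the real totals and levels. The rule passed 0 of 71 genes changed 2-fold, 33 of 66 changed 8-fold (50%), 59 of 63 changed 16-fold (93.7%) and 0 of 1965 unchanged genes. The simulation held no variation between libraries, so the 0 of 1965 is not a false-positive rate of the real data.

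The genes named were fixed by rule: in each mouse library the 10 genes with the most positions, the 12 genes on each side with the largest log2 ratio among those passing, the 10 densest 100-base windows per library and the 5 densest in both, and members of the preset lists with at least 10 positions, of which up to 4 per list are given with values. The 16 mouse lists were Purkinje cell, granule cell, neuronal and synaptic, glia, spermatid, meiotic, piRNA pathway, Sertoli and Leydig cell, blood, microglia with endothelium and smooth muscle, small-RNA and cleavage machinery, textbook cleavage, ribosomal proteins, mitochondrial genome, histones and oxidative phosphorylation. Each list was also summed without the member that moved its fold most, a step chosen after the data were seen. Each list median was ranked among 10000 random lists matched on level in 20 bins. Genes named for the number of shared positions, and members of lists or windows singled out for not passing, were chosen after their values were seen. A result that the rule would name is not reported here.

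Shared positions were counted at the same chromosome, strand and base, and set against 100 draws in which each testis position was moved by 10 to 100 bases in either direction. Alternatives covered the scaling, the minimum number of positions, the fold bound, the pseudocount, the gene spans, the strand, the match of positions and the reading of every base of an interval. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.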

Results

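Degradome sequencing reads the 5′ ends of uncapped polyadenylated RNA, which include the ends left where a transcript had been cut or trimmed. Positions were listed for 3 libraries, 1 of each kind: cerebellum and testis of BALB/c mice aged 6 months, and H1, an established human embryonic stem cell line. The title of the series gives its question, which transcripts of mammals are cut internally and which small RNAs direct the cuts. The cerebellum library held 214332 positions, the testis library 137437 and the H1 library 129112. The entries carried no read count, so the level of a gene is given here as its number of distinct positions, and the reads behind each position are unknown. With 1 library per group no test between tissues was possible, and differences are those between libraries. The 95% intervals given below are exact (Clopper-Pearson) and cover counting error only, since positions from amplified reads are not independent molecules.

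The first comparison asked where in the mouse genome the positions of each tissue fell. Protein-coding gene spans held most of both libraries, with 76.3% of cerebellum positions (76.1 to 76.4) and 62.0% of testis positions (61.7 to 62.3) inside the span of 1 protein-coding gene and no other gene. Long non-coding RNA genes held 8.30% of testis positions (8.16 to 8.45) and 2.30% of cerebellum positions (2.24 to 2.36). Sequence outside every listed gene held 10.1% of testis positions (9.97 to 10.3) and 2.82% of cerebellum positions (2.75 to 2.89). The mitochondrial chromosome held 1.03% of testis positions (0.976 to 1.08) and 0.272% of cerebellum positions (0.250 to 0.294), while pseudogene spans held 7.15% (7.02 to 7.29) and 7.76% (7.65 to 7.87).

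Chromosome X held 3.80% of cerebellum positions and 2.27% of testis positions, a 1.68-fold difference (1.61 to 1.75). Chromosome 14 held 5.85% of testis positions and 3.70% of cerebellum positions, a 1.58-fold difference the other way (1.53 to 1.63). Within genes the positions lay mostly on a single strand. Of the 1925 genes with at least 20 cerebellum positions, 1814 held them all on one strand, as did 900 of 1004 such genes in testis. In those protein-coding genes, 61.6% of cerebellum positions and 58.2% of testis positions lay in the last 25% of the gene span, read in the direction of the strand with most positions, and 8.87% and 11.0% lay in the first 25%. How reads that match several places were handled is not given in the sources used here, so values of genes with near-identical copies are uncertain.

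**Figure D1:**
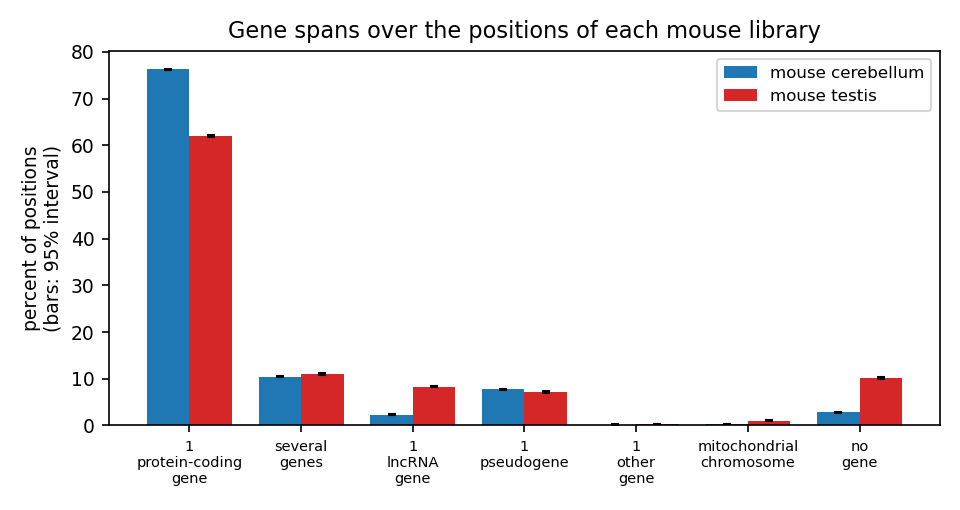
Percent of positions of the cerebellum library (blue) and the testis library (red) by the gene spans that cover them, with exact 95% intervals as bars. Spans of 1 long non-coding RNA gene held 2.30% of cerebellum and 8.30% of testis positions, and sequence with no listed gene held 2.82% and 10.1%.

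The second comparison asked which genes differed in positions between cerebellum and testis. Syne1, which encodes a spectrin-repeat protein of the nuclear envelope, held the most cerebellum positions of any gene, 831 against 9 in testis (59.2-fold relative to library totals, 31.0 to 130). Map2, which encodes a microtubule-binding protein of dendrites, held 517 against 16 (20.7-fold), the kinesin gene Kif5c held 420 against 12 (22.4-fold), the dynein heavy chain gene Dync1h1 held 414 against 13 (20.4-fold) and the myosin gene Myo5a held 340 against 10 (21.8-fold). When every base of each interval was counted, the log2 ratio of Kif5c was 3.75 instead of 4.41 and that of Dync1h1 was 3.53 instead of 4.28, and with the strand with most positions only, that of Myo5a was 5.02 instead of 4.36. Most of the largest ratios belonged to genes with 0 testis positions. The myelin gene Mobp held 228 (at least 48.7-fold more), the GABA receptor gene Gabrb2 held 214 (at least 45.7-fold), the tau gene Mapt held 205 (at least 43.8-fold) and the transcription factor gene Zic1 held 176 (at least 37.6-fold). The myelin basic protein gene Mbp held 180 against 0 where its span overlaps no other gene, but its log2 ratio of 7.40 was 2.94 when only protein-coding spans were used and positions in non-coding genes that overlap it counted.

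Other genes with the largest ratios on this side were Ank1, Gabra6, Kcnd2, Secisbp2l, Eef1a2 and Eno2, with 117 to 153 positions against 0. With protein-coding spans only, the log2 ratio of Ank1 was 4.97 instead of 7.17, so its 0 in testis, like that of Mbp, rested on leaving out positions in overlapping spans. Of the 10 genes with the most cerebellum positions, Camk4 (416 against 15, 17.8-fold), the glutamate transporter gene Slc1a2 (404 against 8, 32.4-fold) and the inositol trisphosphate receptor gene Itpr1 (363 against 4, 58.2-fold, log2 ratio 5.64, or 4.91 with every base) also had more in cerebellum by the rule of size. Both RNA-binding protein genes among the 10, Sfpq (346 against 95, 2.34-fold, 1.86 to 2.96) and Ddx5 (327 against 72, 2.91-fold, 2.25 to 3.81), did not pass it.

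Long non-coding RNA genes led the testis library. Gm36617 on chromosome 15 (59246207 to 59291951) held 426 testis positions against 37 in cerebellum (18.0-fold, 12.8 to 25.9). Gm40402 held 368 against 16 (35.9-fold), Gm10505 held 364 against 16 (35.5-fold), Gm16976 held 303 against 10 (47.3-fold) and Gm2762 held 247 against 19 (20.3-fold). The gene 1700001L05Rik held 242 against 14 (27.0-fold) and Gm21388 held 239 against 28 (13.3-fold). The log2 ratio of Gm21388 was -3.68, or -4.36 in a single random draw of cerebellum down to the testis number. The other genes among the 10 with the most testis positions were Cyp19a1, which encodes aromatase (317 against 30, 16.5-fold), 1700016C19Rik (181 against 10, 28.2-fold) and the RNA helicase gene Ddx19b (178 against 13, 21.4-fold, log2 ratio -4.31, or -3.61 with every base).

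The largest ratios on the testis side were those of Spz1, a transcription factor gene of the germ line, with 106 positions against 0 (at least 55.1-fold more), and Pmfbp1, whose protein joins the sperm head and tail, with 143 against 1 (223-fold, 39.4 to 8869). The log2 ratio of Pmfbp1 was -6.76, or -5.86 when every base of each interval was counted. It was -7.71 when cerebellum was drawn down to the testis number of positions. That draw was made once at random, so the value rests on whether the 1 cerebellum position of Pmfbp1 was drawn. Gm14244 held 115 against 1 (179-fold, 31.6 to 7144) and Gm30236 held 89 against 1 (139-fold, 24.3 to 5543). Gm19663, 4933402J07Rik, 4921509C19Rik, Gm14147, Gm6729, 4930570E03Rik, D130017N08Rik and Tescl held 44 to 71 testis positions and 0 in cerebellum, which gives bounds from at least 22.9-fold to at least 36.9-fold. Gm19663 is annotated as a pseudogene, so its value is uncertain.

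Of the 20203 genes with a position in either mouse library, 2171 held at least 30 over both. By the rule of size, an exact interval of the ratio of library shares wholly beyond 4-fold, 322 of them had more positions in cerebellum, 289 had more in testis and 1560 passed on neither side. Protein-coding genes made up 308 of the 322 and 219 of the 289, and long non-coding RNA genes 10 and 51. The testis count was 0 in 88 of the 322 genes and the cerebellum count was 0 in 15 of the 289. The balance of the sides depended on the settings: with a minimum of 10 positions, 338 genes had more in cerebellum and 456 had more in testis, with totals over genes the numbers were 278 and 302, with a minimum of 100 positions they were 139 and 53, and with the interval beyond 2-fold they were 640 and 407. The bounds against 0 assume that 0 listed positions could stand for up to 3, and whether a position needed a minimum of reads to be listed is not given in the sources used here.

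**Figure D2:**
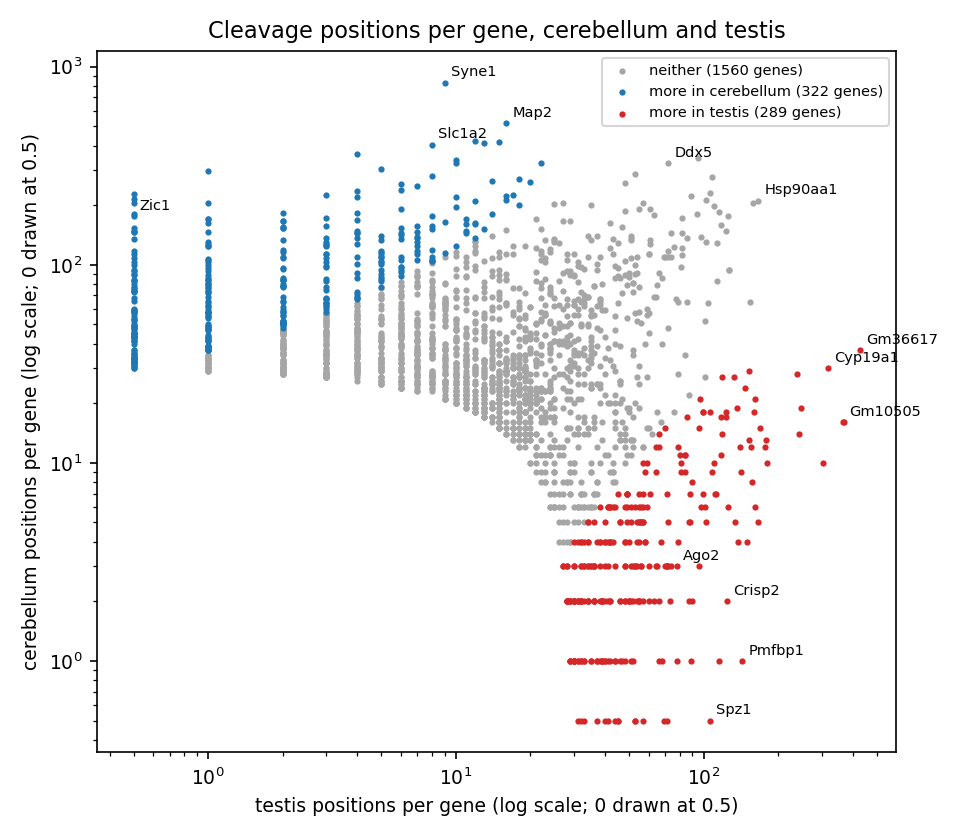
Testis positions (x axis, log scale) against cerebellum positions (y axis, log scale) for the 2171 genes with at least 30 positions over both libraries, with 0 drawn at 0.5. Blue points are the 322 genes with more in cerebellum, red points the 289 with more in testis and grey points the 1560 on neither side; Syne1 held 831 cerebellum positions and Gm36617 held 426 testis positions.

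Gm10505, mapped here after its values were seen, lay in a region dense in testis positions of opposite strands. Its span is on chromosome 17 (27325196 to 27344832). Between 27310001 and 27380000 the testis library held 756 positions on the plus strand and 244 on the minus strand, while the cerebellum library held 34 and 22. To the left of the gene 244 testis positions were on the minus strand and 1 on the plus strand, while the 364 inside it and the 391 to its right were all on the plus strand. The 10 kb from 27360001 to 27370000, which no listed gene covers, held 254 testis positions.

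**Figure D3:**
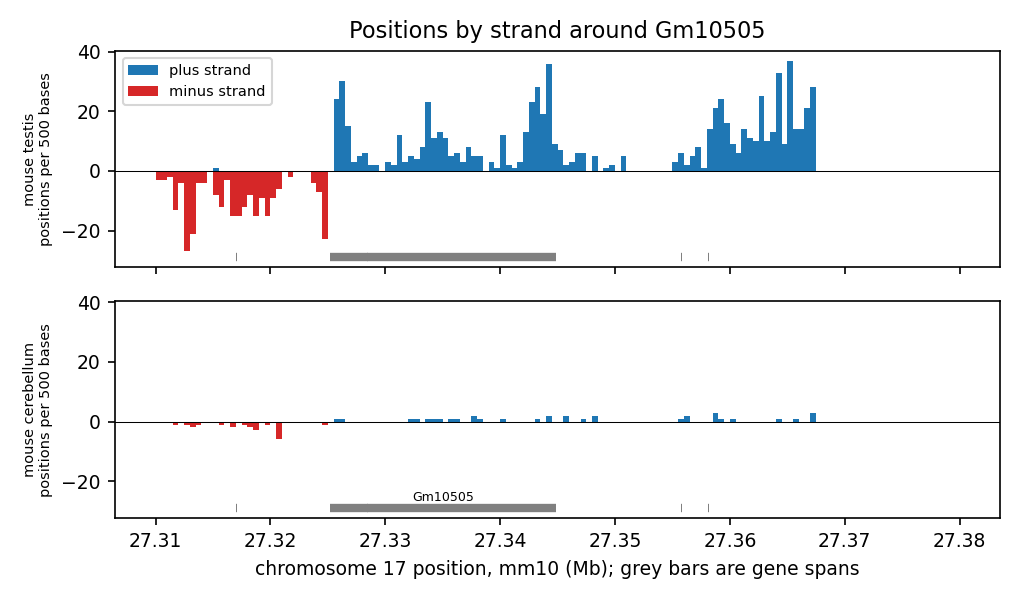
Positions per 500 bases on chromosome 17 from 27310001 to 27380000 (mm10), with plus-strand positions above 0 in blue, minus-strand positions below 0 in red, testis in the upper panel and cerebellum in the lower, and gene spans as grey bars. Testis held 756 plus-strand and 244 minus-strand positions here and cerebellum 34 and 22.

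The gene lists fixed before the data were examined asked whether markers of the cell types of each tissue differed together. Purkinje cell genes had more cerebellum positions: 6 of 7 members with enough positions passed, and the list held 939 positions against 13 (46.3-fold, 27.0 to 87.3). Car8 held 204 against 1 and Calb1, the calbindin gene, held 113 against 0 (at least 24.2-fold). Granule cell genes held 528 against 5 (67.7-fold, 28.8 to 209), and 3 of 4 passed, namely Zic1, Gabra6 and Zic2 (103 against 0, at least 22.0-fold). Neuronal and synaptic genes held 1610 against 35 (29.5-fold, 21.1 to 42.5), and 9 of 11 passed, with Snap25 at 170 against 1 and Stmn2 at 124 against 1. Genes of oligodendrocytes and astrocytes held 1392 against 61 (14.6-fold, 11.3 to 19.2), and 6 of 7 passed, with Slc1a3 at 219 against 4, while glutamine synthetase (Glul, 99 against 44) did not, and without it the list had a fold of 48.8 (30.3 to 84.0).

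Germ cell genes had more testis positions. Spermatid genes held 507 testis positions against 57 in cerebellum (13.9-fold, 10.5 to 18.6), and 4 of 6 passed: Crisp2 (124 against 2, 96.7-fold), Odf2 (140 against 12, 18.2-fold), the protamine gene Prm1 (38 against 1, 59.3-fold) and the transition protein gene Tnp2 (41 against 6, 10.7-fold). Prm2 (51 against 11) and Tnp1 (19 against 18) did not pass. Meiotic genes held 484 against 155 (4.87-fold, 4.06 to 5.87), and 3 of 5 passed, with Hspa2 at 112 against 7, Ldhc at 84 against 11 and Hormad1 at 51 against 3. Sycp1, a synaptonemal complex gene, held 127 against 94 (2.11-fold, 1.60 to 2.78) and did not pass, and without it the list had a fold of 9.13 (6.94 to 12.2). Genes of the piRNA pathway held 239 against 67 (5.56-fold, 4.23 to 7.41), and 1 of 3 passed, Piwil2 (52 against 3, 27.0-fold), while Piwil1 (52 against 12) did not.

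Markers of other cell types were few. Sertoli and Leydig cell genes held 97 testis positions against 110, which relative to library totals is 1.38-fold more in testis (1.04 to 1.82), and Clu, also expressed in brain, gave 48 and 89 of them (3.64-fold more in testis without it, 2.14 to 6.39). Blood genes held 37 cerebellum positions against 7 (3.39-fold, 1.49 to 9.01) and genes of microglia, endothelium and smooth muscle held 45 against 25 (1.15-fold, 0.693 to 1.96), or 22 against 25 without Flt1 (0.564-fold, 0.303 to 1.04). No member of these last lists had enough positions for the rule.

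Ribosomal protein genes, which most cells use, held 1583 cerebellum positions against 778 (1.30-fold, 1.20 to 1.42), and 0 of 29 members passed on either side. Oxidative phosphorylation genes of the nucleus held 2653 against 919 (1.85-fold, 1.72 to 2.00), and 3 of 48 passed: Atp5a1 (212 against 16) and Atp5b (151 against 13) had more in cerebellum and Cox8c (2 against 29) had more in testis. Genes of the mitochondrial genome held 1353 testis positions against 526 (4.01-fold, 3.62 to 4.44), and 8 of 14 passed with more in testis, with COX1 at 160 against 18 (13.9-fold) and ATP6 at 90 against 8 (17.5-fold). On chromosome 1 (24610001 to 24620000), 303 of 393 testis positions and 58 of 441 cerebellum positions matched mitochondrial ones at one alignment. How reads that match several places were handled is not given. The 4.01-fold and the folds of single members, those of COX1 and ATP6 among them, are therefore uncertain beyond their intervals. ND5, with 158 testis and 205 cerebellum positions, did not pass, but these counts take both strands. From base 10001 of the mitochondrial chromosome onward, where ND5 lies, 236 of 357 cerebellum positions and 48 of 474 testis positions were on the minus strand. Histone genes held 125 testis positions against 115 (1.70-fold more in testis relative to library totals, 1.31 to 2.20), and 0 of 2 passed. H1f0, a replacement histone that the symbol rule also caught, gave 64 of the cerebellum positions. Without it the list held 3.64-fold more in testis (2.60 to 5.16). Only H1f0 was left out there, and H1f7, with 11 testis positions against 0, was kept.

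Among genes of small-RNA and cleavage machinery, Ago2, which encodes the slicing Argonaute, held 78 testis positions against 3 in cerebellum (40.5-fold, 13.4 to 201) and was 1 of 2 members with enough positions. Ago3 held 53 cerebellum positions against 7 (4.86-fold, 2.20 to 12.7) and did not pass. The list held 190 cerebellum positions against 177, which relative to library totals is 1.45-fold more in testis (1.18 to 1.79), but this direction rested on Ago2, without which it held 187 against 99 (1.21-fold more in cerebellum, 0.944 to 1.56). The list median was 0.02 on the log2 scale, or -0.13 when scaled to positions in genes outside the mitochondrial chromosome. Transcripts with a textbook cleavage event held 31 cerebellum positions against 10 (1.99-fold, with an interval that includes 1, or 5.13-fold without Dgcr8, 1.56 to 26.6), of which N4bp1 gave 20 and 3, and none had enough positions for the rule.

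Each list was also placed among 10000 random lists of the same size and similar level, as a description of these libraries. The median log2 ratio of cerebellum over testis was 5.01 for Purkinje cell genes, 3.57 for granule cell genes, 4.82 for neuronal genes and 4.90 for glial genes, all at percentile 100. It was -3.54 for spermatid genes (percentile 0), -2.32 for meiotic genes (0.10), -2.12 for piRNA pathway genes (0.40), -0.77 for the mitochondrial genome (0.80) and 0.94 for oxidative phosphorylation (99.9). The other 7 of the 16 lists lay between percentiles 2.5 and 97.5, at 3.79 for Sertoli and Leydig cell genes, 10.2 for histones, 47.0 for small-RNA machinery, 75.3 for ribosomal proteins, 81.1 for microglia, endothelium and smooth muscle, 93.4 for textbook cleavage and 96.2 for blood. With members of at least 30 positions only, meiotic genes (3.27), piRNA pathway genes (12.5) and oxidative phosphorylation (90.4) came inside those bounds, and the mitochondrial genome did so when every base of each interval was counted (10.3). Histones went outside them with a pseudocount of 20 per 1000000 (0.025), with every base (0.035) and with protein-coding spans only (1.59), Sertoli and Leydig cell genes with every base (0.935), and blood under 3 settings (97.7 to 98.1). The median of the mitochondrial genome was -2.67 over members with at least 10 positions, -2.82 over those with at least 30 and -2.90 with protein-coding spans only.

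The third comparison asked how often both tissues had the same position. Hsp90aa1, a heat shock protein gene, held 46 shared positions, the most of any gene, followed by the chaperonin gene Tcp1 with 42, Zranb1 with 32, the heat shock protein gene Hsp90b1 with 31 and the RNA-processing genes Rbm39 and Ythdc1 with 27 each. In all, 15496 positions had the same chromosome, strand and base in both libraries, 11.3% of testis positions (11.1 to 11.4) and 7.23% of cerebellum positions (7.12 to 7.34). After the testis positions were moved by random offsets of 10 to 100 bases, 1596 ± 37.4 coincided (SD over 100 draws), so the observed number was 9.71 times the shifted one. At an offset of 1 base 3545 coincided, at 2 bases 4767, at -2 bases 4891, at 10 bases 2972 and at 100 bases 952. Counts at near offsets lay above the shifted mean, so the 9.71 is larger than the excess over nearby bases.

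The 100-base windows with the most positions in both libraries lay in Rn18s-rs5, a ribosomal RNA gene (20 in cerebellum and 17 in testis), in Skp1, a ubiquitin ligase subunit (18 and 15), in Hsp90aa1 (17 and 15), in Gm10925 (15 and 21) and between genes on chromosome 1 (24613801 to 24613900, 15 and 15). Both chromosome 1 windows lie in 10 kb in which 77.1% of testis positions and 13.2% of cerebellum positions matched mitochondrial positions of the same library at one constant alignment, so their origin is uncertain. In genes with positions in both tissues, 12833 of 98103 testis positions were shared (13.1%, 12.9 to 13.3). When positions up to 2 bases apart counted as shared, the number was 28606, and when any overlap of the listed intervals counted it was 24034.

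**Figure D4:**
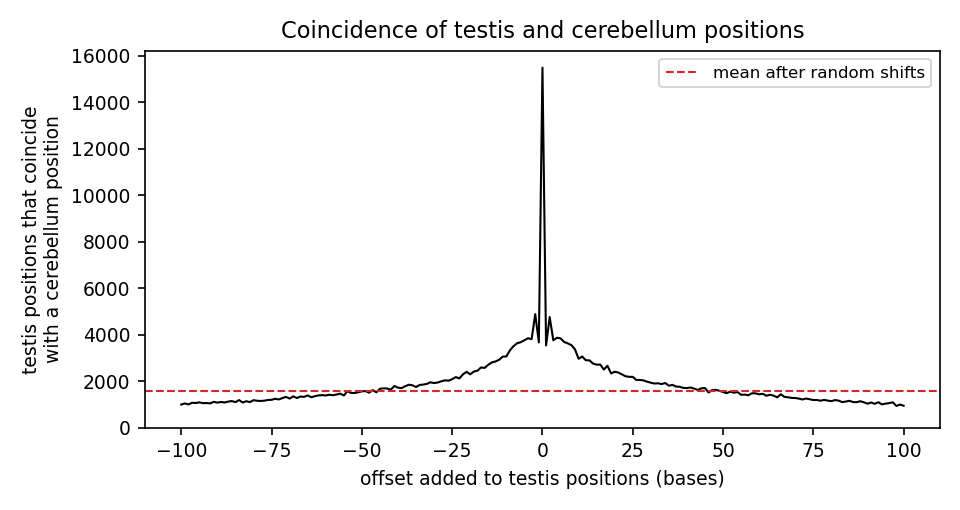
Number of testis positions that coincide with a cerebellum position on the same strand (y axis) after an offset of -100 to 100 bases is added to the testis positions (x axis), with the mean after random shifts as a dashed line at 1596. The count was 15496 at no offset, 3545 at an offset of 1 base and 4767 at 2 bases.

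Within each mouse library, single genes held the densest 100-base windows. In cerebellum, A330023F24Rik, whose span holds Mir29c, had 24 positions in 1 window, the glycolytic gene Aldoc 22, the transferrin gene Trf 21, and Spock2, Cct5, Rn18s-rs5, Atp5a1 and Kif5c 20 each. ND5 of the mitochondrial genome had 21, as did 1 window of chromosome 1 outside gene spans (24614901 to 24615000). In testis, Slc25a41 had 21, Gm10925 21, Fam209 20, and Spz1, 1700012D01Rik, Gm3526 and Mif 19 each. The other testis windows among the densest 10 lay in the mitochondrial genome, with 21 and 20 positions in ATP6 and 20 in a window that ATP8 and ATP6 each cover in part.

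H1 cells were described alone, by coordinates of hg19. The densest 10 kb of the nuclear chromosomes lay on chromosome 1 (560001 to 570000, 474 positions), followed by chromosome 1 (62670001 to 62680000, 228 positions, all on the plus strand), chromosome 7 (121710001 to 121720000, 196, all on the minus strand), chromosome 17 (79470001 to 79480000, 183, all on the minus strand) and chromosome 7 (26230001 to 26240000, 182, all on the minus strand). The densest nuclear 100 bases lay on chromosome 19 (11172501 to 11172600, 25 positions). Chromosome 1 held 13.7% of the positions (13.5 to 13.9), chromosome 17 7.64%, chromosome 19 6.92% and the mitochondrial chromosome 1.31% (1.25 to 1.38). These shares are of a partial set: no positions on chromosomes 3 and 11 were analysed here, those of chromosomes 2, 5, 7 and 12 were on the minus strand only and those of chromosome 6 on the plus strand only. On chromosomes with both strands, 49.0% of positions were on the minus strand (48.7 to 49.3). Genes of H1 were not analysed here.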

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

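The tests of strand balance and of divergent neighbours were chosen only after the result was seen.

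The testis library held 13923 positions outside every listed gene span, a signal the gene comparisons did not use, against 6052 in cerebellum, and 64.0% of them fell in 226 windows of 10 kb with at least 10 such positions, among them chromosome 4 (57350001 to 57360000, 247) and chromosome 6 (81890001 to 81900000, 233). Genomic DNA would give both strands about evenly, but the median share of the more frequent strand in these windows was 100% and 185 of the 226 held a single strand. The strands of positions in sparser windows were not tested, so a share of genomic DNA among those could not be judged. Of the testis positions, 57.7% lay within 5 kb of a gene span (56.8 to 58.5) against 18.3% of random bases outside spans, which leaves 42.3% farther away. In cerebellum the share was 68.4% (67.3 to 69.6). Unlisted 3′ extensions of known genes may be among them. The share cannot tell these from other sequence near genes, because both ends of a span and either strand were taken. Divergent transcription units may account for part of the testis positions outside spans. Among neighbouring windows, 13 pairs had minus-strand positions on the left and plus-strand positions on the right and 2 had the opposite order (exact two-sided binomial p = 0.00739), against 0 and 2 in cerebellum. Listed genes could lie between the windows of a pair, as Gm10505 does on chromosome 17 (27320001 to 27350000). Extensions of divergent listed genes would give the same order, so the binomial p cannot tell these from unlisted divergent units. The difference in tissue, confounded with the library, stays open and was not tested.

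The densest testis window outside gene spans, chromosome 1 from 24610001 to 24620000, held 265 positions outside spans and 393 in all, of which 77.1% (72.6 to 81.2) coincided with testis mitochondrial positions at one inverted alignment, short of the 80% set beforehand for calling them shared. In testis 303 positions coincided at that alignment and 74 at the next best. The same window held 441 cerebellum positions, of which 58 coincided (13.2%, 10.1 to 16.7) against 37 at the next best alignment, and the densest nuclear 10 kb of H1 held 474, of which 146 coincided (30.8%, 26.7 to 35.2) against 105.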

How the results depend on the processing

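Chosen after the data were seen were every base of each interval, whole-interval overlap, protein-coding spans alone, the strand with most positions, drawing cerebellum down to the testis number, H1 chromosomes with both strands, scaling of the lists, and each list without the member that moves its fold most. Counting every base gave 349165, 218853 and 201409 bases for cerebellum, testis and H1. It put 76.0% of cerebellum and 63.2% of testis bases in 1 protein-coding span, 2.74% and 9.20% outside genes, and 1.57% of H1 on the mitochondrial chromosome. Where protein-coding genes took precedence, their shares were 85.4% and 71.5%. On H1 chromosomes with both strands the minus share was 49.0% and the mitochondrial share 1.61%. A minimum of 10 positions gave 338 and 456 genes with more in cerebellum and testis, a minimum of 100 gave 139 and 53 because fewer genes enter, and an interval beyond 2-fold gave 640 and 407, which put 42.6%, 72.4% and 61.1% of passing genes on the cerebellum side against 52.7%. Sharing was 28606 within 2 bases and 24034 by interval overlap. The median of small-RNA machinery turned to -0.11 with every base, for which the cause was not tested, and to -0.13 with totals over genes. That scaling changes the ratio of levels by the same factor in every gene. The log2 ratios still moved unequally, because a fixed amount is added to both sides after scaling. The log2 ratio of Map2 fell from 4.32 to 4.17 and that of Spz1 from -7.28 to -7.64, while that of Mobp rose from 7.74 to 7.95. Mobp had no testis positions, so its testis side was the fixed amount alone and its rise is not a gain over other genes. Without 1 member, the fold of cerebellum over testis turned to 1.21 for small-RNA machinery (Ago2) and to 0.564 for microglia, endothelium and smooth muscle (Flt1). That fold rose from 46.3 to 74.9 for Purkinje cell genes (Shank2) and from 67.7 to 112 for granule cell genes (Slc17a7). For blood it rose from 3.39 to 5.29 (Hbb-bs).

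Under the other alternatives run, the genes with more in cerebellum numbered 261 to 458 and those with more in testis 234 to 398. Totals over genes moved the median log2 ratio of genes with enough positions by -0.13, from 0.60 to 0.48, and put 47.9% of passing genes on the cerebellum side. Of the named genes, 9 lost their call at a minimum of 100 positions and 1 gained one at 2-fold. Lists outside percentiles 2.5 to 97.5 numbered 6 of 10 with enough members at a minimum of 30 positions, 9 of 13 at 10 and 9 to 11 of 16 otherwise. No paired analysis was possible because each group had 1 library. Alternatives that need read counts, exons or a genome were not run, nor was TMM. The number of positions limits the rule: changes of 8-fold passed in 33 of 66 simulated genes.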

Other observations

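The tests of hairpin processing, of paralogs and of base periodicity were chosen only after the result was seen, as were the small RNA genes described here.

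Small nucleolar RNA genes held positions at or just inside their 5′ ends in both mouse tissues. The 5′ and 3′ ends of small RNA genes are here the edges of the span read along the strand of each position, because the gene table gives no strand. Within 2 bases of the 5′ end the testis library held 57 positions, against 1 in 5 bases upstream and 4 in 5 bases farther inside, both 26 to 30 bases away. The cerebellum library held 215, against 6 upstream and 178 inside (1.21-fold), and also had 92, 69 and 72 positions at bases 4, 5 and 6 past the end. Of 1340 such genes, 206 had a position there in cerebellum, 54 in testis and 42 in both, where 8.30 would be shared if the tissues were independent. An array of 206 of these genes on chromosome 7 (59347173 to 59980945) differed between tissues, with 760 cerebellum positions, all on the minus strand, against 5 in testis (97.5-fold, 41.6 to 301). Its copies are repeats, so the split among them is uncertain. In the array the cerebellum positions numbered 124 at the 5′ end and 159 at 26 to 30 bases inside. Outside it they numbered 91 at the end, 19 inside and 6 upstream. Over all 1340 genes, bases 28 and 30 past the end held 60 and 85 cerebellum positions, and bases 7 to 25 held 1 to 12 each. The inside bases thus held peaks of their own. Neither the 1.21-fold nor the 159 therefore sets the 5′ end against an even level. Outside the array, 82 genes had a position at the 5′ end in cerebellum, 53 in testis and 41 in both, against 3.83 by independence. The 8.30 and 3.83 take in genes with no position in either tissue. An excess over them therefore cannot tell shared ends from expression of the same genes in both tissues.

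Transcripts that host miRNAs held positions at the 3′ side of the hairpin. Mir29c had 11 cerebellum positions within 20 bases of its 3′ end and 2 in testis, Mir3074-1 had 9 and 1, Mir24-1, which it overlaps, had 8 and 1, Mir29b-2 had 6 and 1, and Mir9-2 had 6 and 0.

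Over 1228 annotated miRNA genes, with each position counted once where hairpins overlap, the cerebellum library held 213 positions within 20 bases of a 3′ end and 65 within 20 bases of a 5′ end, a ratio of 3.28 (2.47 to 4.40), or 3.14 (2.33 to 4.28) without the 5 hairpins that had most. Coverage that rises along the host transcript would give as large a ratio farther out, but it was 1.57 (1.09 to 2.27) at 100 to 140 bases outside. A feature of any small RNA gene would also appear in cerebellum at small nucleolar RNA and tRNA genes. These had ratios of 0.0603 (0.0420 to 0.0840) and 0.548 (0.285 to 1.02). The first cannot decide this, because it is set by the positions at 5′ ends described above (614 against 37 at 3′ ends). The tRNA ratio showed no excess at 3′ ends. It rests on 17 positions against 31, with 20 near both kinds of end left out. Testis held 100 against 36 at miRNA genes, a ratio of 2.78 (1.88 to 4.19, exact two-sided binomial p = 3.72e-08), but tRNA genes had a ratio of 2.47 there (1.32 to 4.84), so the testis excess was not particular to hairpins. Cutting of the precursor at the base of the hairpin may account for the excess in cerebellum, as a hypothesis found and tested on the same data.

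The cerebellum library held 1518 positions in 274 of the 289 genes with more in testis. Reads shared with paralogs could not be told apart from other sources, since the share of these genes with at least 1 position (94.8%) is the pattern itself. Carry-over of testis molecules would repeat testis positions. In the preset spermatid list 6 of 57 did (10.5%, 3.96 to 21.5), and of the 1518, 24.1% did (22.0 to 26.3). That share lay below the level set beforehand for carry-over as the cause. Its interval spans the 25% set beforehand as the bound under which carry-over would be set aside. Carry-over could therefore not be told apart from other sources over this set. Low expression of these genes in cerebellum may account for the pattern, since testis positions in genes with more in cerebellum coincided to a similar degree, 21.6% (19.1 to 24.2). The 24.1% and 21.6% were 5.16 and 4.83 times the shares after random shifts, against 6.09 and 6.08 times for cerebellum and testis positions in genes on neither side, but carry-over in both directions would give the same similarity.

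A periodicity of 3 bases along transcripts was not found in all libraries: spacings that are multiples of 3 exceeded their neighbours in 22 of 32 cases in cerebellum, 21 of 32 in testis and 17 of 32 in H1, with exact two-sided binomial p of 0.0501, 0.110 and 0.860.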
